A study of Mus musculus with 16 samples.

How the data were processed

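RNA of 16 mouse B cell samples was measured on Affymetrix mouse exon arrays, 1 array per sample. Per the labels, 4 samples are normal B cells from spleen and 12 are Myc-induced B lymphoma cells from lymph node, all from mice of a hybrid strain background. Each set holds a p53 -/- genotype (here p53-null) and a p53 246/- genotype (here p53-246), giving 4 groups: 2 p53-null and 2 p53-246 normal samples, and 6 p53-null and 6 p53-246 lymphomas. Per the labels, B cells were obtained by magnetic depletion of other cells, RNA was taken up in Trizol and cleaned on columns, and cDNA was made with a whole-transcript amplification kit. Tissue of origin and the naming of the arrays differ exactly as cell type does, so no comparison of lymphoma with normal cells can separate them. The labels do not state that the samples of a group come from separate animals, so the p-values measure the spread between these samples.

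The authors' table of values was used as it stands. It holds 23332 transcript clusters on 16 arrays, with deposited values from 2.508 to 13.5, read here as log2 intensities. The log base is not stated in the sources used here: natural logarithms would put the highest intensity at 726214, far above the usual range of an array scanner, so log2 was taken. The method of summary, background treatment and normalization is not given in the sources used here. Per the submitters' processing notes, Partek 6.5 and the mouse build mm8 were used, with no step named for either, and the design text names a mixed model analysis of variance without its random term. No further transformation was made before the fits.

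Of the 23332 transcript clusters, 14996 carry exactly 1 gene symbol, 1019 carry several and 7317 carry none in the table of names used here. Genes were tested once each, by the brightest of their single-symbol transcript clusters over all arrays, which left 14860 genes. The identifiers of 14941 single-symbol transcript clusters matched the reference table of assembly GRCm38.p6, which was used only for current names, chromosomes and neighbours. Trp53 has no transcript cluster under a single symbol and is not analysed here. Transcript clusters with several symbols or none entered only an alternative fit of the whole table.

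The medians of the arrays over all transcript clusters were 5.35 and 5.26 in p53-null normal cells, 5.27 and 5.28 in p53-246 normal cells, 5.22, 5.15, 5.14, 5.06, 5.14 and 5.14 in p53-null lymphomas 1 to 6, and 5.14, 5.19, 5.14, 5.10, 5.18 and 5.29 in p53-246 lymphomas 1 to 6. The standard deviation over genes was 1.57 in p53-null normal sample 1 and 1.56 in p53-246 lymphoma 6, and 1.69 to 1.94 on the other arrays. These 2 arrays are called the narrow arrays below. The median of 800 olfactory and vomeronasal receptor genes, taken as the background level, was 4.21 and 4.43 on the narrow arrays and 3.66 to 4.08 on the others. Sex was read from the Y-linked gene Eif2s3y: each lymphoma group holds 4 females and 2 males, the p53-null normal samples are both male and the p53-246 normal samples are 1 male and 1 female.

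Differences were tested in R 4.3.3 with limma 3.58.1. A linear model with a mean for each of the 4 groups was fitted to all 16 arrays, contrasts were taken, variances were moderated by empirical Bayes, and p-values were adjusted over the 14860 genes by the Benjamini-Hochberg method, two-sided, with a threshold of 0.05. The contrasts were genotype in lymphomas, genotype in normal cells, lymphoma against normal cells with both genotypes averaged and within each genotype, and the interaction of genotype and cell type. Log2 differences are p53-246 minus p53-null or lymphoma minus normal. Errors given as SE are moderated standard errors of these differences. The pipeline was tested on simulated data of the same layout with 200 changed genes. The simulated genes varied independently, each with the same spread on all arrays. The shares recovered below thus do not cover narrow arrays or genes that move together. In the simulation 1.5-fold changes were recovered for 47.5% of the changed genes and 2-fold changes for 89.0% in the lymphoma genotype contrast, for 0 and 49.5% in the normal genotype contrast, and for 57.5% and 90.0% in lymphoma against normal cells. The median 95% interval of a log2 difference reached a factor of 1.22, 1.41 and 1.22 to either side in these contrasts, and 1.49 for the interaction.

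Gene groups were 31 lists, 19 of pathways and 12 of cell type markers, tested with camera of limma on the same model with the preset inter-gene correlation of 0.01 and p-values adjusted over the 31 lists of a contrast. Beside the camera test stand the numbers of members past the threshold over all genes and, where that number differs, adjusted over the list alone. On simulated data, 5 of 5 lists of 25 genes shifted by 0.5 on the log2 scale were called and 0 of the others. The simulated genes varied independently and the lists were random. The simulation therefore does not test how often camera calls lists whose genes move together, or arrays of narrow spread. For the lymphoma genotype contrast each list's mean per array was also tested by exact permutation over the 924 assignments of the 12 lymphomas, where the smallest possible p is 0.00216. The correlation between genotype effects, the count of genes near Trp53 and median shifts per chromosome were computed as well.

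The comparisons, tests, lists and alternatives were chosen before the data were examined, except those stated as added. Genes were named by rule: of the genes past the threshold whose higher group mean lies above the low-value cutoff of 4.583, the 12 with the largest rise and the 12 with the largest fall per contrast, or the 6 with the smallest p in each direction where none passed. The text names those the space allows. Immunoglobulin and T cell receptor segments, microRNA, small nucleolar RNA, olfactory and vomeronasal receptors and placeholder symbols were left out of this choice, which removed 183 called genes. Of each list, the members with the largest changes and members past the threshold could be named. Samples far from the rest of their group were searched for with Dixon's test in each lymphoma group, on the list means, Myc, the spread of values and the chromosome shifts. A chromosome shift was flagged only if it also lay beyond the size limit and all random lists given below.

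The alternatives tried were quantile normalization, centring each array on its median, leaving out genes with a mean under that cutoff (leaving 9906), all transcript clusters, an unmoderated linear model, array weights, a trended and robust variance prior, the replicate number as a block, sex as a covariate, each array left out in turn, a fold threshold of 2, the arrays of each comparison alone, and for lists an estimated correlation and averaged transcript clusters. Added after seeing the data were fits without the narrow arrays, fits with the spread of each array as a covariate, a chromosome reference of the 12 lymphomas with and without genes of low mean, and 9 gene families, of which 1 is not reported here. Exon-level values, splicing, and immunoglobulin and T cell receptor segments were not used here. Copy number was not measured.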

Results

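The data are expression profiles of 16 mouse samples: normal spleen B cells and Myc-induced B lymphoma cells, each from p53-null mice (p53 -/-) and from p53-246 mice (p53 246/-). There are 2 normal samples and 6 lymphomas per genotype. Lymphomas and normal cells differed in 5685 genes, and no single gene passed the threshold between the genotypes in either cell type. The first principal component carried 60.9% of the variance and the next 12.0%. The correlation between a lymphoma and a normal array was 0.83 to 0.91, against 0.95 to 0.99 between 2 lymphomas and 0.96 to 0.99 between 2 normal samples.

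The genes with the largest rises in lymphoma cells over normal B cells (12 lymphomas, 4 normal samples, both genotypes averaged) include several kinases of the cell cycle. Pbk, a mitotic kinase, rose by 4.91 on the log2 scale (SE 0.15, 30.1-fold). The spindle checkpoint kinases Bub1 (4.49, SE 0.12), Bub1b (4.2, SE 0.12) and Ttk (3.85, SE 0.15) rose, as did the replication checkpoint genes Chek1 (4.22, SE 0.12) and Clspn (3.97, SE 0.14). Further genes with large rises were Mnd1 of meiotic recombination (4.67, SE 0.31), the deoxycytidylate deaminase Dctd (4.54, SE 0.18), asparagine synthetase Asns (4.39, SE 0.20), the noncoding RNA Airn (4.33, SE 0.26), Pter (4.23, SE 0.36) and the Myc target Cdca7 (3.85, SE 0.16). In normal cells Mnd1 and Pter lie under the low-value cutoff of 4.583, near background, so their rises are lower bounds. All genes named here have an adjusted p under 0.05 in limma, of 5685 genes past that threshold (3036 higher, 2649 lower, 38.3% of 14860 tested), among them 1332 at least 2-fold higher and 775 at least 2-fold lower. The balance of higher and lower depends on the setting: 3384 and 1964 with centred arrays, 3038 and 3246 with array weights, 3287 and 3852 without p53-246 lymphoma 6, and 2965 and 3526 without p53-null normal sample 2.

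Surface receptors of resting mature B cells stood at the other end. The complement receptor Cr2 fell by 6.49 on the log2 scale (SE 0.16, 89.7-fold) and the low-affinity IgE receptor Fcer2a by 6.13 (SE 0.13, 70.2-fold, adjusted p = 3.0e-15, limma). Rasgrp3, an activator of Ras below the B cell receptor, fell by 6.15 (SE 0.18), and Fcrl5, Cd200, Tlr7 and Gimap8 fell by 5.34 (SE 0.14), 5.02 (SE 0.24), 5.13 (SE 0.33) and 5.06 (SE 0.22). Kynu of tryptophan breakdown fell by 5.37 (SE 0.41), the platelet chemokine Ppbp by 5.30 (SE 0.24), Rasgef1b by 4.92 (SE 0.13), Ms4a6c by 4.78 (SE 0.43) and the kinase Lrrk2 by 4.45 (SE 0.38). In lymphomas Cr2, Fcer2a, Rasgrp3, Fcrl5, Cd200, Kynu and Rasgef1b lie under the low-value cutoff, near background, so these falls and folds are lower bounds. The same arrays hold lower values of natural killer cell, macrophage, dendritic cell and platelet markers in the lymphomas, given below, so falls of genes that such cells carry are measured beside those.

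Myc itself was lower in the lymphomas. Its transcript cluster had a mean of 5.99 (SD 0.22, n = 12, range 5.72 to 6.42) in lymphomas and 8.28 (SD 0.48, n = 4, range 7.91 to 8.95) in normal cells, a fall of 2.29 on the log2 scale (SE 0.14, 4.90-fold, adjusted p = 6.3e-10, limma). Which Myc sequence drives the lymphomas, and whether this transcript cluster measures it, is not given in the sources used here.

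The gene groups of growth and division rose together. All 35 measured mitosis genes were past the threshold upward (median log2 difference 3.02, camera adjusted p = 3.5e-35), with Birc5 at 3.32 (SE 0.11) and Ccna2 at 3.42 among them. Of the DNA replication list 34 of 35 rose and 0 fell (median 2.30, adjusted p = 4.3e-26), led by Uhrf1 (3.69, SE 0.21), Dtl (3.31, SE 0.12), Pole (3.22, SE 0.18) and Mcm3 (2.95, SE 0.18). All 31 ribosome biogenesis genes rose (median 1.67, adjusted p = 3.0e-22), with Wdr12 at 2.60 (SE 0.21) and the polymerase I subunit Polr1b at 2.49 (SE 0.17). Nucleotide synthesis rose in 24 of 26 genes with 1 lower (median 1.89, adjusted p = 4.4e-17), led by the CTP synthase Ctps (3.73, SE 0.13) and Ppat of purine synthesis (2.83, SE 0.13). The DNA repair list rose in 25 of 32 genes, 26 adjusted over the list alone (median 1.04, adjusted p = 2.4e-13), with Brca1 at 2.17 (SE 0.15). The DNA repair call has an adjusted p = 0.0610 with an estimated correlation.

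Energy and protein turnover moved the same way. Oxidative phosphorylation rose in 20 of 21 genes (median 1.12, camera adjusted p = 3.7e-13), with Cox7b at 1.77 and Ndufa1 at 1.76, and the proteasome in 25 of 26 (median 1.10, adjusted p = 1.0e-16). Sterol synthesis rose as a list with 8 of 18 genes higher (median 0.30, adjusted p = 0.0206), among them Sqle at 1.41 (SE 0.24) and Cyp51 at 1.0. The sterol call has an adjusted p = 0.379 with an estimated correlation, 0.0585 after quantile normalization and 0.521 with array spread in the fit. Glycolysis had 7 genes higher and 2 lower of 14 (3 lower adjusted over the list alone, median 0.34, adjusted p = 0.0558), with the lactate carrier Slc16a1 at 3.03 (SE 0.16) and Tpi1 at 2.77 (SE 0.29) higher and Hk1 lower by 0.92. The unfolded protein response list had 6 genes higher and 5 lower of 21 (8 and 5 over the list alone, adjusted p = 0.448), with Dnajb9 lower by 2.16 and Xbp1 by 1.0 on the log2 scale.

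Mature B cell identity genes fell. Of 24 mature B cell markers 21 fell and 0 rose (median log2 difference -2.14, camera adjusted p = 4.0e-12). Besides Cr2 and Fcer2a, the follicle homing receptor Cxcr5 fell by 4.08 (SE 0.11), Ccr6 by 3.37, the activation marker Cd83 by 3.39 (SE 0.15), Ms4a1 (CD20) by 2.59 (SE 0.29), Cd22 by 1.95 (SE 0.31) and the lineage factor Pax5 by 1.04 (SE 0.19). Cd79a of the B cell receptor, at -0.57 (SE 0.45, adjusted p = 0.330), did not pass. The germinal centre list fell with 1 gene higher and 6 lower of 13 (median -0.63, adjusted p = 0.00940), with Rgs13 lower by 4.02 (SE 0.20), Bcl6 by 3.13 (SE 0.12) and Lmo2 by 2.04, and the chromatin enzyme Ezh2 higher by 1.81 (SE 0.12). In lymphomas Cxcr5, Ccr6, Cd83, Rgs13 and Bcl6 lie near background as well, so their falls are lower bounds. The germinal centre call has an adjusted p = 0.0539 with an estimated correlation.

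The lists of earlier and later B cell stages did not pass. The pro-B and pre-B list had 6 genes higher and 3 lower of 16 (camera adjusted p = 0.338), with Myb higher by 2.30 (SE 0.13) and Bach2 lower by 1.97 (SE 0.28). The plasma cell list had 4 higher and 3 lower of 14, 5 and 4 adjusted over the list alone (adjusted p = 0.644), with Slamf7 higher by 1.58.

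Antigen presentation and interferon genes fell as well. All 5 measured MHC class II genes were lower (median log2 difference -2.39, camera adjusted p = 0.000187): H2-Oa by 3.37 (SE 0.19), H2-Ab1 by 2.40, H2-Aa by 2.39 and the invariant chain Cd74 by 2.37 (SE 0.28). Of 27 interferon-stimulated genes 26 fell and 0 rose (median -1.84, adjusted p = 5.4e-11), with Ifitm3 at -3.27 (SE 0.49), Trim30a at -2.80 and the nucleic acid sensor Zbp1 at -2.72 (SE 0.17). Both calls have an adjusted p = 0.10 with an estimated correlation. MHC class I presentation had 1 gene higher and 4 lower of 10, 1 and 5 over the list alone (adjusted p = 0.220; 0.0283 after quantile normalization and 0.00653 with array spread in the fit), with Tap1 lower by 1.52 and B2m by 0.57 and the peptidase Erap1 higher by 0.69.

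Genes of stimulation and homing fell. NF-kB targets were lower in 15 of 18 and higher in 0 (median log2 difference -1.24, camera adjusted p = 2.1e-09), with Cd40 lower by 2.67. The NF-kB call has an adjusted p = 0.0539 with an estimated correlation. Immediate early genes had 2 higher and 17 lower of 23, 18 lower over the list alone (median -0.91, adjusted p = 1.5e-07), with the phosphatase Dusp1 lower by 2.73 (SE 0.20), Jun by 2.67 (SE 0.14), Klf6 by 2.36, Zfp36 by 2.34 and Fos by 1.85 (SE 0.16), and Nr4a2 and Gadd45b higher by 0.83 and 0.63; Jun and Fos in lymphomas and Nr4a2 and Gadd45b in normal cells lie under the low-value cutoff. Adhesion and migration genes had 1 higher and 14 lower of 23, 15 lower over the list alone (median -0.78, adjusted p = 1.0e-05), with the oxysterol receptor Gpr183 lower by 3.38 (SE 0.18).

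The p53 target list did not pass with the genotypes averaged: 3 genes higher and 11 lower of 34 (median log2 difference -0.17, camera adjusted p = 0.110; 0.0283 after quantile normalization and 0.00653 with array spread in the fit). Casp1 was lower by 3.86 (SE 0.63), Trim7 by 3.09 (SE 0.11), the growth arrest gene Gadd45a by 1.31 (SE 0.15) and Mdm2 by 0.60 (SE 0.19), Plk2 was higher by 2.26 (SE 0.37), and the cell cycle inhibitor Cdkn1a was at -0.17 (SE 0.12, adjusted p = 0.278). Cdkn1a lies under the low-value cutoff in all 4 groups, so little can be read from it here or in the genotype comparisons, and Trim7 does so in lymphomas. Of 23 genes reported as raised by mutant p53, 9 were higher and 5 lower (adjusted p = 0.231), with Vegfa higher by 1.82 and Egr1 lower by 1.64. The Bcl2 family and caspase list had 4 higher and 8 lower of 25, 5 and 8 over the list alone (adjusted p = 0.662). Of its members Bcl2 fell by 1.90 (SE 0.15) and the caspase 8 regulator Cflar by 1.82, and the pore former Bak1 rose by 1.13.

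Markers of other cell types moved between lymphomas and normal cells. Natural killer cell markers fell (8 lower of 11, 10 over the list alone, median log2 difference -0.52, camera adjusted p = 0.00277), with Tyrobp lower by 1.92 (SE 0.36) and Gzma by 1.70. Macrophage and monocyte markers fell (8 lower of 20, median -0.45, adjusted p = 0.00545), with Cybb lower by 4.33 (SE 0.58) and Adgre1 by 1.92. Dendritic cell markers fell (5 lower of 10, 6 over the list alone, median -0.64, adjusted p = 0.0112), with Clec9a lower by 1.90, and so did platelet markers (7 lower of 9, median -0.72, adjusted p = 0.00136), with Pf4 lower by 1.52 (SE 0.31). Gzma, Clec9a and Pf4 lie under the low-value cutoff in lymphomas. With an estimated correlation these 4 calls have an adjusted p = 0.189, 0.379, 0.181 and 0.225.

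Neutrophil markers went up, with 7 higher and 1 lower of 17 (median log2 difference 0.36, camera adjusted p = 0.0312): the calprotectin genes S100a9 (3.76, SE 0.34) and S100a8 (3.52, SE 0.39), Ngp (2.51) and Lcn2 (2.25) rose, and Il1b fell by 0.85. The neutrophil call has an adjusted p = 0.482 with an estimated correlation, 0.0911 without the narrow arrays and 0.188 with array spread in the fit. The normal samples differed widely. The neutrophil mean was 5.02 and 5.97 in p53-null and 4.87 and 5.44 in p53-246 normal samples 1 and 2, against 5.86 to 6.69 in lymphomas. In p53-null normal cells the SD was 2.25 for S100a8 and 1.64 for S100a9. T cell markers had 0 higher and 2 lower of 19, 1 over the list alone (Cd5 at -0.55 and Gata3 at -0.30, adjusted p = 0.481). Erythroid markers had 1 higher and 3 lower of 14, 2 lower over the list alone (adjusted p = 0.448), with the transferrin receptor Tfrc higher by 2.21. Stroma and endothelium had 1 higher and 4 lower of 27 (adjusted p = 0.101), with Fn1 lower by 1.82 and Pecam1 by 1.52.

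**Figure D1:**
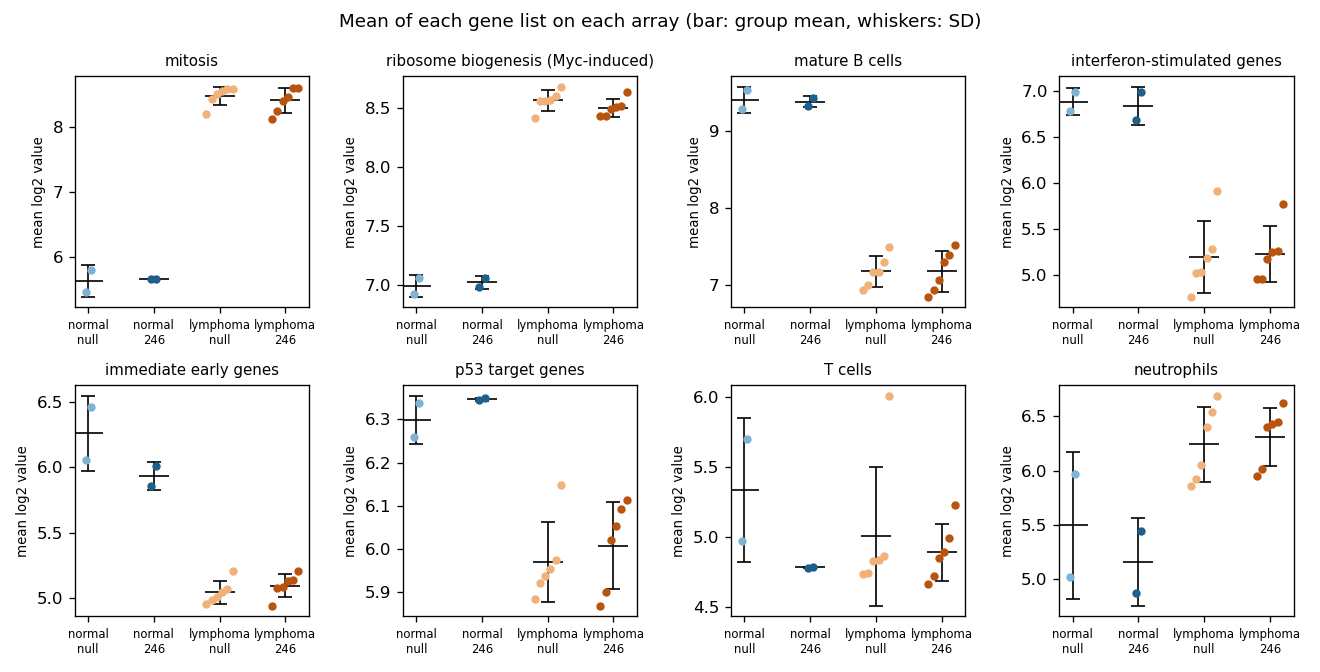
Mean log2 value of 8 gene lists on each array (dots), with the mean (bar) and SD (whiskers) of the 4 groups along the horizontal axis. In lymphomas the mitosis list lies at 8.44 and the mature B cell list at 7.17, against 5.65 and 9.40 in normal cells.

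Each genotype was also compared with its own normal samples. In p53-null cells (6 lymphomas, 2 normal samples) Pbk rose by 5.12 (SE 0.21, 34.9-fold) and Bub1 by 4.61, with the centromere gene Cenpn at 3.96 (SE 0.28) and Ctps at 3.95 (SE 0.19). Cr2 fell by 6.41 (SE 0.23, 85.3-fold), Fcer2a by 6.04 (SE 0.18) and Trim30b by 5.0 (SE 0.50). Fcer2a and Trim30b lie under the low-value cutoff in p53-null lymphomas, so their falls are lower bounds. In p53-246 cells (6 lymphomas, 2 normal samples) Pbk rose by 4.70 (SE 0.21, 26.0-fold), S100a9 by 4.67 (SE 0.49), S100a8 by 4.03 (SE 0.56) and the prostaglandin reductase Ptgr1 by 3.83 (SE 0.60). Cr2 fell by 6.56 (SE 0.23, 94.4-fold), Fcer2a by 6.22 (SE 0.18) and Rgs13 by 4.52 (SE 0.28). Cr2, Fcer2a and Rgs13 are near background in lymphomas, as above. S100a8 and Ptgr1 lie under the low-value cutoff in p53-246 normal cells, so their rises are lower bounds. The neutrophil list passed in the p53-246 contrast (7 higher, 0 lower of 17, camera adjusted p = 0.0133; adjusted p = 0.412 with an estimated correlation) and had an adjusted p = 0.0901 in the p53-null contrast; its interaction did not pass (adjusted p = 0.0602). The interaction of Ptgr1, S100a8 and S100a9 with genotype did not pass, as for all genes. The p53 target list had medians of -0.14 in the p53-null contrast (2 higher, 7 lower of 34, adjusted p = 0.189) and -0.18 in the p53-246 contrast (1 higher, 5 lower, adjusted p = 0.0490; adjusted p = 0.0991 with an estimated correlation), and its interaction did not pass (adjusted p = 0.747).

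In limma 4737 genes passed in p53-null cells (2600 higher, 2137 lower) and 3738 in p53-246 cells (2161 higher, 1577 lower). Of these, 3257 passed in both (2006 higher and 1251 lower in both, against 378.1 and 226.8 for independent lists), and the log2 differences of the contrasts, which share no array, correlated at r = 0.92 (Spearman 0.76). Without p53-null normal sample 1 the p53-null count is 2856. Without p53-246 normal sample 1 or 2 the p53-246 count is 2418 or 2407. The order of the counts turns with array weights (3172 in p53-null and 6180 in p53-246 cells), without the narrow arrays (3365 and 4828), with array spread in the fit (4306 and 4473) and without p53-null normal sample 1 (2856 and 3803). Centring moved the share of higher genes in the p53-null contrast from 54.9% to 66.9% (2941 higher, 1452 lower), and the median log2 difference of lymphoma against normal cells over all genes from -0.09 to 0.0088.

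**Figure D2:**
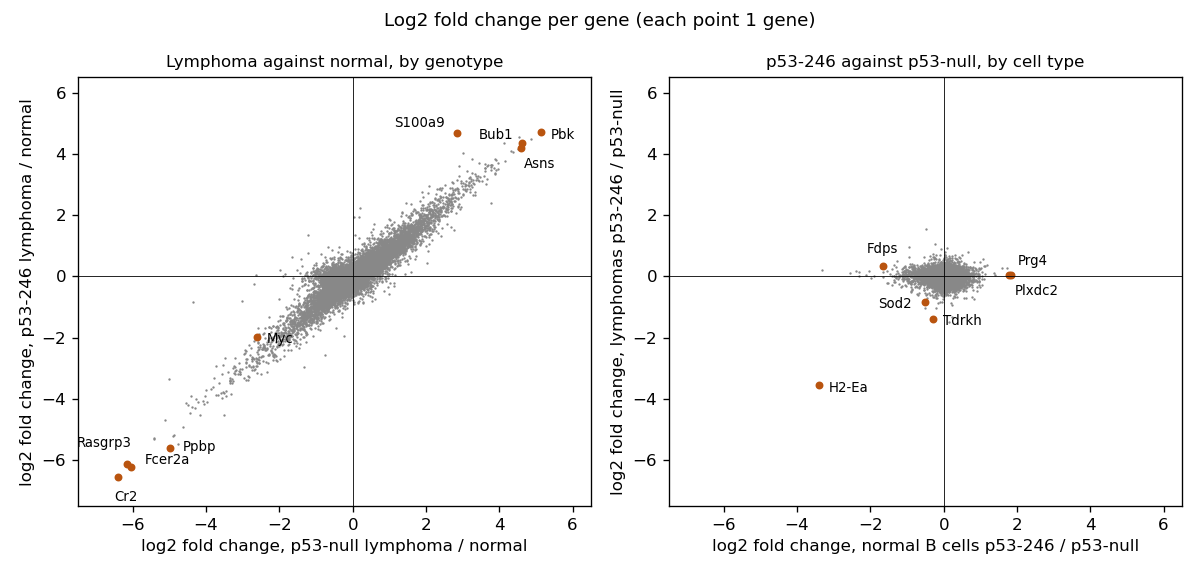
Each dot is 1 gene. Left, log2 difference of lymphoma and normal cells in p53-null (horizontal) and p53-246 (vertical) samples, r = 0.92; right, log2 difference of p53-246 and p53-null in normal cells (horizontal) and lymphomas (vertical), r = -0.063.

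Between p53-246 and p53-null lymphomas (6 and 6) the genes with the smallest p were, downward, the mitochondrial superoxide dismutase Sod2 (log2 difference -0.83, SE 0.18, unadjusted p = 0.000333), the replication protein Rpa2 (-0.49, SE 0.11), the Toll signalling inhibitor Irak3 (-0.56, SE 0.13), Tdrkh of the piRNA pathway (-1.38, SE 0.35), Rhbdd1 (-0.37) and the methionyl tRNA synthetase Mars1 (-0.36). Upward they were Tmem151a (0.36, SE 0.10), Armcx2 (0.34), Gdpd1 (0.69, SE 0.20), the NF-kB regulator Nkiras2 (0.44), Ptms (0.43) and the p53 cofactor Ppp1r13b (0.36). All have an adjusted p = 0.994 in limma, so these are values and not changes. Tdrkh, Armcx2 and Tmem151a lie under the low-value cutoff in 1 of the groups. Myc was at -0.06, Cdkn1a at 0.08 (SE 0.12) and Mdm2 at -0.25 (SE 0.19). Of 14860 genes 0 passed, 445 had an unadjusted p under 0.05 where 743 are expected by chance, and an unmoderated linear model gave 0 and 448.

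The p53 target list had 0 of 34 genes past the threshold between the lymphoma genotypes (median log2 difference 0.04, camera adjusted p = 0.736), and the list of genes reported as raised by mutant p53 had 0 of 23 (median -0.05, adjusted p = 0.309). Small shifts of whole lists did pass with the preset correlation. DNA replication was lower in p53-246 lymphomas (median -0.15, adjusted p = 4.1e-08), with Rpa2 at -0.49, Mcm7 at -0.44 and Gins2 at -0.39, and so was oxidative phosphorylation (median -0.17, adjusted p = 3.8e-05), with Ndufv1 at -0.50, Ndufb5 at -0.32 and Ndufa9 at -0.31. The DNA replication mean was 7.60 and 7.61 in p53-246 lymphomas 2 and 6, against 8.03 to 8.18 in the other p53-246 lymphomas. It was 7.85 to 8.27 in p53-null lymphomas, so the lower mean rests largely on p53-246 lymphomas 2 and 6. Further lists past the threshold were the proteasome (-0.07, adjusted p = 0.000821), DNA repair (-0.08, 0.00244), mitosis (-0.08, 0.00310), nucleotide synthesis (-0.08, 0.00359), ribosome biogenesis (-0.07, 0.0155), the unfolded protein response (-0.07, 0.0196), sterol synthesis (-0.08, 0.0416), erythroid markers (0.11, 0.00954) and NF-kB targets (0.13, 0.0196). In p53-246 lymphoma 6, a narrow array, the proteasome mean was 9.20 and the mitosis mean 8.12, against 9.27 to 9.57 and 8.20 to 8.60 in the other lymphomas. The erythroid mean of p53-246 lymphoma 6 was 5.54, against 4.79 to 5.15 in the others. The proteasome, mitosis and erythroid shifts thus rest in part on 1 array. The NF-kB mean was 6.07 in p53-246 lymphoma 2 and 5.30 to 5.49 in all 11 other lymphomas, so this shift rests largely on 1 array. Over all genes 0 members of the 11 lists passed; adjusted over the list alone 1 did, Rpa2 of DNA replication, downward. Every one of the 11 has an adjusted p of at least 0.800 with an estimated correlation.

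By exact permutation of list means over the lymphomas the smallest p was 0.0541, for oxidative phosphorylation (adjusted p = 0.966). Only DNA replication and oxidative phosphorylation stayed past the threshold without the narrow arrays (adjusted p = 0.0129 and 0.0135), after quantile normalization (0.00358 and 0.0479) and with array spread in the fit (0.00716 and 0.0162). Of the lymphomas, leaving out the narrow arrays removes only p53-246 lymphoma 6. It keeps p53-246 lymphoma 2, which also had a low DNA replication mean. T cell markers in p53-null lymphoma 6 had a mean of 6.01, against 4.74 to 4.87 in the other p53-null lymphomas.

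In normal B cells (2 and 2) the smallest p belonged to Plxdc2, a membrane receptor (log2 difference p53-246 minus p53-null 1.77, SE 0.32, unadjusted p = 4.4e-05, adjusted p = 0.654 in limma). Others upward were Tcta (1.10, SE 0.25), the lubricin gene Prg4 (1.84, SE 0.44), Pigz (0.58), the small GTPase Rap1a (0.89) and Lzts1 (0.79). Downward stood Fdps of sterol synthesis (-1.64, SE 0.42), Elovl7 of fatty acid elongation (-1.24), Plpp6 (-0.98), Slc9c1 (-0.86), Enkur (-0.82) and the CD30 ligand Tnfsf8 (-0.76), all but Plxdc2 with an adjusted p = 0.999. Fdps, Elovl7, Slc9c1 and Tnfsf8 lie under the low-value cutoff in p53-246 normal cells. Of 14860 genes 0 passed, 505 had an unadjusted p under 0.05, and an unmoderated linear model gave 0 and 494. Without p53-null normal sample 2, which leaves the narrow array as the only p53-null normal sample, 532 genes passed (35 higher, 497 lower), among them Fdps (-2.55, adjusted p = 0.000756), Plxdc2 (1.70, adjusted p = 0.0292) and Myc (-1.02, adjusted p = 0.0462). Without p53-246 normal sample 1, 4 genes passed: Prg4 (2.87, adjusted p = 0.00146), Plxdc2 (2.31, adjusted p = 0.0185), Baiap2l1 (1.53, adjusted p = 0.0341) and the interferon-induced Trim30b (-3.08, adjusted p = 0.000138).

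Of the lists, immediate early genes (median log2 difference -0.38, camera adjusted p = 6.8e-07) and T cell markers (-0.37, adjusted p = 0.000284) were lower in p53-246 normal cells and platelet markers higher (0.28, adjusted p = 0.000769), with 0 members past the threshold in each. With an estimated correlation the adjusted p = 0.347, 0.891 and 0.891. The chains of the T cell receptor complex Cd3g, Cd3e and Cd3d stood at -1.56, -0.90 and -0.84, and the mean of the T cell list was 4.97 and 5.70 in p53-null and 4.78 and 4.79 in p53-246 normal samples 1 and 2. In the same order the immediate early list had 6.46 (the narrow array), 6.05, 6.01 and 5.86, with the p53-null samples first, and the platelet list 5.64, 5.43, 5.57 and 6.29, so the higher platelet mean rests on p53-246 normal sample 2. In the sterol synthesis list 0 genes passed over all genes and 1 passed over the list alone, Fdps, both here (downward) and in the interaction (upward). In p53-null normal cells Fdps had a mean of 5.10 with SD 1.28 and was higher on the narrow array, so both calls rest largely on that array.

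The interaction asks whether the genotype difference itself differs between lymphomas and normal cells. The smallest p upward belonged to Enkur (1.05, SE 0.23, unadjusted p = 0.000256), with Slc9c1 (0.98), Fdps (1.98, SE 0.49), Tnfsf8 (0.93), the splicing factor Sf3b4 (1.76) and the myeloid and B cell factor Spi1 (1.32). Downward stood Plxdc2 (-1.73, SE 0.37, unadjusted p = 0.000241), Tcta (-1.20), Rplp0 (-0.88), Osgep (-1.23), Prg4 (-1.81) and Pigz (-0.58). All have an adjusted p = 0.997 in limma. Of 14860 genes 0 passed, 540 had an unadjusted p under 0.05, and an unmoderated linear model gave 0 and 467. Without p53-null normal sample 2, 473 passed (445 higher, 28 lower), and without p53-246 normal sample 1, 2 passed: Prg4 (-2.84, adjusted p = 0.00612) and Trim30b (3.32, adjusted p = 0.000193).

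Across genes the genotype differences of lymphomas and of normal cells correlated at r = -0.063 (Spearman -0.11). Of 100 splits of the lymphomas, the real one included, 54 gave a correlation as far from 0. Among the 304 tested genes within 10 Mb of Trp53, 2 belonged to the 100 genes with the smallest p in the lymphoma contrast, where 2.05 are expected (Fisher exact p = 1), and 1 in the normal contrast (Fisher exact p = 0.726).

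**Figure D3:**
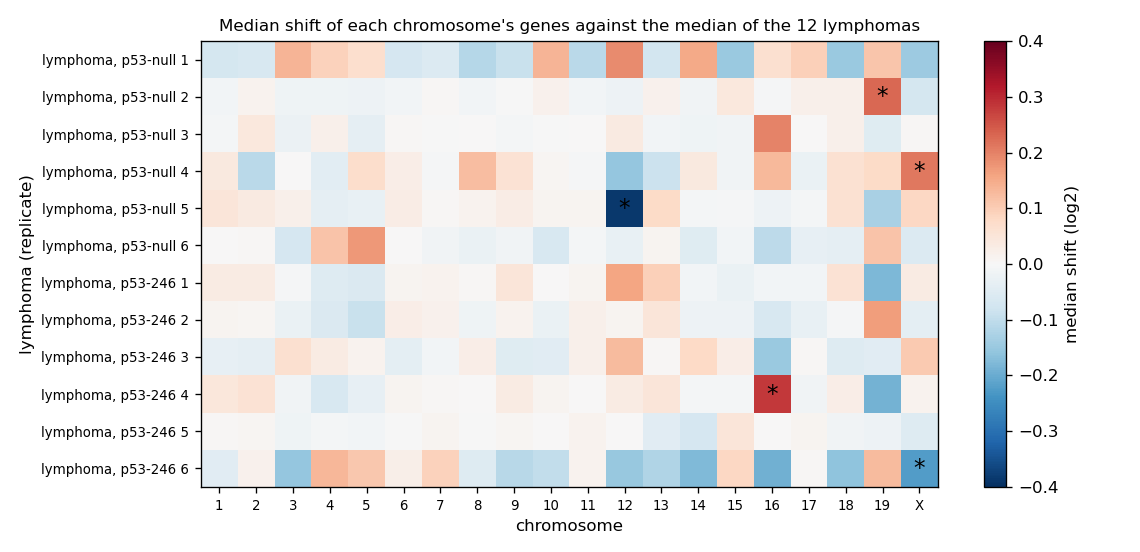
Median log2 shift of the genes of each chromosome (columns) in each of the 12 lymphomas (lines) against the median of the lymphomas, without genes of low mean; stars mark shifts beyond 0.2 and beyond all of 1000 random gene lists. Lower values stand out for chromosome 12 in p53-null lymphoma 5 (-0.386) and higher ones for chromosome 16 in p53-246 lymphoma 4 (0.282).

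Single lymphomas differed in the level of whole chromosomes. Against the mean of the normal arrays the chromosome medians ranged from -0.15 to 0.14. Against the median of the 12 lymphomas and without genes of low mean, a setting chosen after seeing the data, 5 of 240 pairs of chromosome and lymphoma lay beyond 0.2 and beyond all random lists: chromosome 12 in p53-null lymphoma 5 (-0.386, 322 genes, 90.7% of them lower), chromosome 16 in p53-246 lymphoma 4 (0.282, 321 genes, 75.4% higher), chromosome 19 in p53-null lymphoma 2 (0.229, 363 genes, 82.1% higher), and X in p53-null lymphoma 4 (0.212) and p53-246 lymphoma 6 (-0.224, a narrow array). After scaling each array the shifts of X are 0.158 and -0.180, under the limit of 0.2. Shifts of these autosomes that lay beyond all random lists but under 0.2 include chromosome 16 in p53-null lymphoma 3 (0.199), chromosome 12 in p53-null lymphoma 1 (0.189) and chromosome 19 in p53-246 lymphomas 4 (-0.190) and 1 (-0.180). The random lists were drawn from genes of like mean level. These are values without a test, and copy number was not measured.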

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

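Chosen only after the result was seen were the tests of Myc and of the chromosome shifts, the counts of splits, the fit without the narrow arrays and the reading of the estimated correlation, itself planned, as a test of the 11 lists; the fit with array spread was added after the data were seen, with its reading set down before its result.

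Myc was lower in lymphomas than in normal B cells. A weak response of the transcript cluster is excluded, since its mean on the normal arrays lies 4.33 above the receptor genes' background, and so are the narrow arrays as the whole cause, since without them the log2 difference is -2.16. A raised immediate early program in the isolated normal cells stays open: that list was lower in the lymphomas too, with a median of -0.91. A Myc transcript in the lymphomas that this transcript cluster does not measure was not tested.

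Against the median of the 12 lymphomas and without genes of low mean, autosomes 12, 16 and 19 were each shifted as wholes by more than 0.2 in 1 lymphoma. Shifts in other lymphomas were smaller. This reference was chosen after the data were seen, and it hides shifts that most lymphomas share. The sign of a shift is therefore relative to the other lymphomas and not to normal cells. For the shifts above 0.2, a few strongly changed genes could hardly move a median over all genes of a chromosome, so splitting it could not test them. Each shifted autosome split in its middle did shift in both parts, the smallest by 0.185. That is beyond all random lists of the whole chromosome's size, which vary less than lists of a part's size. Narrow spread is excluded, since the smallest shift after scaling each array is 0.227. A gain or loss of the chromosome stays open as a hypothesis, and no biological explanation was tested.

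Of the 31 lists, 11 passed between p53-246 and p53-null lymphomas. Without the narrow arrays 2 passed, with array spread as a covariate 2, and with an estimated correlation 0, so both uneven spread of the arrays and genes that move together between lymphomas stay open beside genotype. For single genes, 54 of 100 splits of the lymphomas, drawn from 462 and with the real one among them, reached the real 445 genes with an unadjusted p under 0.05. Chance is therefore not excluded. The highest of the other splits gave 2726, several times the real count, which points to a structure of the samples or arrays. It sets p53-null lymphomas 1, 3 and 6 and p53-246 lymphomas 2, 5 and 6 (a narrow array) against the rest. The standard deviation over genes was 1.56 to 1.88 in the lymphomas named and 1.84 to 1.94 in the rest. The split thus largely follows the spread of the arrays, and its cause was not tested. For lymphoma against normal cells, only the real split of the 100, drawn from 784, reached its 5685 genes past adjusted p. The highest other gave 2811. A random split is thus an unlikely cause, to the limit of 1 in 100 that these splits can show.

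Some samples lay far from the others of their group in the mean of a list. They were p53-null lymphoma 5 in p53 targets (6.15, others 5.89 to 5.97), p53-null lymphoma 1 in pro-B and pre-B markers (5.62, others 6.10 to 6.25), p53-null lymphoma 6 in T cell markers (6.01, others 4.74 to 4.87) and natural killer cell markers (5.24, others 4.53 to 4.73), p53-246 lymphoma 6 in stroma and endothelium (4.94, others 4.56 to 4.67) and p53-246 lymphoma 2 in NF-kB targets (6.07, others 5.30 to 5.49). These are 6 of 106 groups tested. By Dixon's test alone chance flags about 1 in 20 groups, or 5.3. Chromosome shifts also had to pass the size limit and all random lists, so 5.3 is too high for the rule used. The number expected under that rule was not computed, so no excess over chance is read from the 6.

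For 9 lists the interaction of genotype and cell type passed the threshold with the preset correlation of camera. The median interaction on the log2 scale was -0.25 for DNA replication (adjusted p = 0.00369), -0.14 for mitosis (0.0242), -0.11 for nucleotide synthesis (0.0433), -0.20 for oxidative phosphorylation (0.00784), -0.14 for the proteasome (0.0371), -0.18 for DNA repair (0.0124), -0.19 for platelets (0.0413), 0.40 for T cells (0.0383) and 0.43 for immediate early genes (8.8e-06). With an estimated correlation all 9 have an adjusted p of at least 0.549. The T cell mean was 5.70 in p53-null normal sample 2 and 4.78 to 4.97 in the other normal samples. The platelet mean was 6.29 in p53-246 normal sample 2 and 5.43 to 5.64 in the others. Immediate early genes had 6.46 on the narrow p53-null array and 5.86 to 6.05 in the others. These interactions thus rest largely on single normal arrays. Fewer lists passed after quantile normalization, as given below.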

How the results depend on the processing

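Tests without the narrow arrays, with array spread in the fit and with the lymphoma reference for chromosomes were chosen only after the data were seen. Of the single genes and lists named under each alternative, 6344 values kept direction and side of the threshold, 49 passed newly, 141 no longer passed and 18 reversed. Of the results per comparison, 188 stayed, 22 moved and 4 passed newly. A count of genes or lists was taken to stay if it lay within a set factor of its main value, so it could still change. In lymphoma against normal cells, 4643 and 7139 genes were thus counted as stayed beside the main 5685. The genotype and interaction counts were 0 in every fit of all arrays and of the subsets named; they moved only when 1 array was left out. Signal over background limits calls of genes near the receptor level, and a single array left in a group is assumed to vary like the other groups. The replicate number as a block left 0 genotype calls, with r between same-number lymphomas from -0.31 to 0.33, so the numbers were not read as pairs. The causes of the moves below were not tested unless the setting itself gives them.

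Above a fold of 2, 2107 genes passed in lymphoma against normal cells, 2309 in p53-null and 1983 in p53-246 cells, because fewer genes meet both limits. With array weights the p53-246 count was 6180. With arrays left out in turn, counts ranged from 0 to 532 (genotype in normal cells), 4643 to 7139 (lymphoma against normal), 2856 to 5676 (p53-null lymphoma against normal), 2407 to 4508 (p53-246 lymphoma against normal) and 0 to 473 (interaction).

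Cdkn1a, near background and never past the threshold, reversed with array spread in the fit in lymphoma against normal cells (0.0315), in p53-null (0.0581) and p53-246 cells (0.0050), and with quantile normalization in p53-null cells (0.0013). Its genotype difference in normal cells was 0.0372 with quantile normalization, 0.0167 centred, 0.16 without the narrow arrays and 0.0608 with array spread, and -0.17 to 0.16 with arrays left out in turn. The lymphoma genotype difference of Myc ranged from -0.12 to 0.0175 in that way.

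With an estimated correlation the lists past the threshold went from 11 to 0 for genotype in lymphomas, 3 to 0 in normal cells, 9 to 0 for the interaction, 20 to 9 for lymphoma against normal, 19 to 9 in p53-null and 20 to 10 in p53-246 cells. With quantile normalization and with array spread they were 2 in lymphomas and 2 for the interaction. Without the narrow arrays they were 2 in lymphomas and 12 in normal cells. Lists that reversed without the narrow arrays were the unfolded protein response in lymphomas (adjusted p = 0.916), stroma (0.0119) and adhesion (0.0463) in normal cells, and mature B cells (0.0234), stroma (0.00623) and the proteasome (0.661) in the interaction. The proteasome interaction also reversed with quantile normalization (adjusted p = 0.985).

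The farthest chromosome shift against normal arrays (p53-246 lymphoma 4, chromosome 19) was -0.15, then -0.38 without genes of low mean, -0.11 against the lymphoma median and -0.19 with both.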

Other observations

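The gene families below and H2-Ea were chosen after values had been seen, and the tests of the families with them.

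Small GTPases of lymphocyte survival fell as a family in lymphoma cells: all 8 measured Gimap genes were lower than in normal B cells (median log2 difference -3.74, camera adjusted p = 1.4e-07 over the 9 families, 0.0135 with an estimated correlation), with Gimap4 lower by 4.34 (SE 0.33) and Gimap6 by 4.34 (SE 0.39). Toll-like receptors fell in 8 of 12 (median -1.15, adjusted p = 6.0e-06). Tlr7, a sensor of RNA, fell by 5.13, the lipopeptide receptor Tlr1 by 3.77 (SE 0.36), Tlr3 by 2.56 (SE 0.11) and the DNA sensor Tlr9 by 1.61 (SE 0.13). Of 3 Fc receptor-like genes 2 fell (median -4.14, adjusted p = 0.00128), among them Fcrl1 at -4.14 (SE 0.30). Macrophage and dendritic cell markers were lower in the lymphomas as well (adjusted p = 0.379 and 0.181 with an estimated correlation), and some of these receptors are carried by such cells.

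Protein synthesis and folding families rose. All 16 of the cytosolic aminoacyl tRNA synthetases tested, which are not the full set, were higher (median 1.30, camera adjusted p = 2.1e-12), with Kars at 1.92 (SE 0.18) and Gars at 1.84 (SE 0.12), and so were 61 of 68 mitochondrial ribosomal proteins (median 1.05, adjusted p = 1.9e-23). Of 8 genes named after the chaperonin CCT, 6 rose (median 1.31, camera adjusted p = 8.6e-06), with Cct3 at 2.51 (SE 0.16). Cct6b (0.12) and the CCT8-like gene Cct8l1 (-0.01) did not pass. The Smc and Ncap genes, most of them of condensin and cohesin, rose in 9 of 12 (median 0.71, adjusted p = 3.1e-06), led by Ncapg2 (3.53, SE 0.18), Ncaph (3.29, SE 0.15), Ncapd2 (2.44, SE 0.16) and Smc2 (2.33, SE 0.09). Kruppel-like factors fell as a family with 1 higher and 6 lower of 15 (median -0.23, adjusted p = 0.0278; adjusted p = 0.0898 with an estimated correlation), Klf3 by 2.74 (SE 0.22) and Klf12 by 1.98 (SE 0.15). Klf12 and Tlr3 lie under the low-value cutoff in lymphomas.

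H2-Ea, the alpha chain of the MHC class II molecule I-E, was the gene farthest from 0 in both genotype comparisons, without passing in either: -3.56 in lymphomas (SE 1.29, adjusted p = 0.994, limma) and -3.40 in normal cells (SE 2.23, adjusted p = 0.999). Per array its values were 11.9 and 11.9 in p53-null and 11.9 and 5.06 in p53-246 normal cells, 10.2, 11.2, 10.7, 10.2, 10.4 and 9.86 in p53-null lymphomas 1 to 6, and 10.3, 3.76, 3.80, 11.2, 4.13 and 8.03 in p53-246 lymphomas 1 to 6. As background, H2-Ea is silent in mice of some H2 haplotypes and expressed in others. No further test was run on these values, and the cause was not tested.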
